A study of Mus musculus with 7 samples.

How the data were processed

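Gene expression was measured by RNA sequencing in the mouse embryonic stem cell line CCE on day 0 and on days 1 to 6 of treatment with retinoic acid. Each of the 7 days had 1 library, so no group had a replicate. Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase, depleted of ribosomal RNA and made into stranded libraries. Reads were aligned with BWA 0.7.3 to the mouse genome build mm9, per the submitters' processing notes. The counting tool, its strand setting, the annotation version and the way the libraries were scaled are not given in the sources used here.

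The deposited values are log2 read values per RefSeq transcript, 1 column per day. Raised from the log, the values of each library were whole multiples of a single step, the worth of 1 read. Every value of up to 1000 reads lay within 0.05 reads of a whole number, which is 100% in each of the 7 libraries. The values therefore are whole counts per transcript multiplied by 1 factor per library and put on the log2 scale. They were not divided by transcript length. A whole number added to the counts before scaling would give the same multiples and cannot be told apart. The factors brought the 7 libraries to nearly the same total. The table held 15296 transcripts of 12071 gene symbols, of which 2124 symbols had more than 1 transcript, and 14960 of the transcripts were coding and 336 noncoding. The lowest value of each library was taken as 1 read. By this reckoning each listed transcript had at least 1 read in all 7 libraries, and each had a HomoloGene number. Genes with no read on some day, which include genes that start or end at 0, were therefore not analysed here or stand at 1 read. Transcripts of a gene can share reads, as can near-identical gene copies and overlapping genes, because the treatment of such reads is not given in the sources used here. Positions were taken from the table, in mm9 and counted from 1.

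The recovered reads came to 10280938 on day 0, 11462785 on day 1, 11198956 on day 2, 9911246 on day 3, 17923852 on day 4, 16503844 on day 5 and 7194325 on day 6, over the listed transcripts only. They set the precision of a difference between 2 libraries, given as an exact binomial (Clopper-Pearson) interval at 95%. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules and culture-to-culture spread was not measured.

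These choices were made before the data were examined: for a symbol with several transcripts the one with the highest mean over the 7 libraries was used, and genes with a mean above the 40th percentile, a mean log2 value of 8.40, were kept, which left 7242. A straight line on day was fitted to the log2 values of each gene with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean trend, 5 residual degrees of freedom), with Benjamini-Hochberg adjustment over all genes kept, and genes were called at an adjusted p under 0.05. Slopes are in log2 units per day with their standard error (SE). Straight or curved courses were tested with limma's moderated F-test of day and day squared together, which also calls straight lines. The curved term alone was not tested. Single days were compared with day 0 by size only, as counts of genes at least 4-fold apart, with no p-value. The correlation of Zfp217 and of each gene of the m6A list with day was tested by exact permutation of the days, two-sided.

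Also fixed were 28 gene lists. The 20 lists with at least 4 genes kept were tested on the slope with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. Fry tests whether a list's genes move 1 way on balance, and does not compare them with other genes. On single days a list's median difference was placed among 10000 random lists of the same size matched on mean expression in 10 bins, as a description of these libraries. The order of Hox gene activation was tested as the Spearman correlation of paralog number with the day of half-maximal rise. With 6 Hox genes kept, this test ran over all 720 orders of the paralog numbers in place of the 100000 resamples first intended.

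Named genes followed a rule. For the trend it took the 12 largest slopes in each direction among called genes whose slope kept its sign when each library was left out, without predicted, clone and small RNA names. For curved courses it took the 8 smallest F-test p among genes with an inner day at least 2 log2 units above or below both ends. For day 1 and day 6 it took the 10 largest differences in each direction among the genes kept. It added Zfp217, the m6A list, up to 4 genes per list and 13 fixed examples. Genes of the lists beyond these were named after their values were seen, as were those named by the same rule over days 0 to 5. The fixed example T was not analysed here.

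After the data were examined, the day 6 library differed from the rest with transcript length. Fits over days 0 to 5 were among the alternatives set beforehand, and fits with a length correction were added: the deviation of each library from the gene mean was fitted by loess (span 0.3) on log2 transcript length and subtracted. Median-centring over days 0 to 5 and limma-voom on the recovered reads were added too. The GC content of transcripts came from a mouse annotation of a different build, matched by RefSeq identifier for 97.5% of the genes kept, and was used as a property of the sequence alone.

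The trend fit was tested on simulated data, with normal noise of each gene's own residual spread, drawn independently for each gene, around its mean and known slopes given to 50 genes each. Of slopes of 0.25, 0.5, 1 and 2 log2 units per day it recovered 4%, 30%, 82% and 96% over 7 libraries, with 4 unchanged genes called in a set of 7242 genes. Over days 0 to 5 it recovered 60%, 82%, 96% and 100%, with 6 unchanged genes called, and no sign was wrong in either. Shifts shared by many genes of a library, such as that of day 6 with transcript length, were not simulated. The counts of unchanged genes called therefore do not cover them. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.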

Results

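RNA was collected daily from CCE, a mouse embryonic stem cell line grown without feeder cells, while it differentiated with retinoic acid, the vitamin A derivative that activates nuclear retinoic acid receptors. On day 0 the cells were kept with leukemia inhibitory factor (LIF), a cytokine that holds mouse stem cells undifferentiated, and received the DMSO vehicle. On days 1 to 6 LIF was absent and retinoic acid was present at 5 µM, per the labels' protocols. Ribosomal-RNA-depleted total RNA was sequenced in 1 library per day, 7 in all, and the labels do not say whether the days were separate cultures. LIF removal, retinoic acid and time in culture changed together, and no later untreated library exists in the design, so a difference from day 0 belongs to all of them. The series title names Zfp217, a zinc finger protein, and N6-methyladenosine (m6A), a methyl mark on RNA, and the time course asks how their genes and the stem cell program behave during differentiation.

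The libraries held from 7194325 recovered reads on day 6 to 17923852 on day 4, with 10280938 on day 0. Between neighbouring days the root mean square log2 difference over 7242 genes was 0.67 from day 0 to day 1, 0.70, 0.45, 0.30 and 0.23 for the next steps, and 2.31 from day 5 to day 6. That last step was 3.29 times the next largest, and 1.83 times after a length correction. The median transcript had 90 reads on day 6, against 241 on day 0 and 498 on day 4. The day 6 minus day 5 difference fell with transcript length across genes (Spearman rho −0.78), while for the other daily steps rho lay from −0.050 to 0.26; genes are not independent replicates, so no p is given. Trends are therefore given over all 7 libraries and over days 0 to 5. Days 0 to 5 were not free of a length trend either, since day 5 minus day 0 had a rho of 0.25 with length.

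Within 1 day, Cyp26a1, Cyp26b1, Stra8 and several Hox genes stood far above day 0, and Tdh, Mycn and Socs3 stood far below it. Cyp26a1, which encodes an enzyme that degrades retinoic acid (NM_007811, chromosome 19, 37772297 to 37776026 in mm9), was 254-fold higher, a log2 difference of 7.99 with a 95% counting interval of 7.24 to 8.86. Its relative Cyp26b1 went from 5.47 to 12.22 on the log2 scale, Dhrs3, a retinaldehyde reductase, from 5.64 to 10.09, and Stra8, a retinoic acid-induced gene of meiotic entry, from 6.07 to 12.70. Among Hox genes, which pattern the body axis, Hoxb2 went from 1 read to 672 (602-fold, log2 interval 6.75 to 14.54) and Hoxa5 from 2 reads to 1283 (575-fold, log2 interval 7.31 to 12.21). A count of 1 read is the lowest of its library and may stand for no read, which leaves such folds uncertain. Hoxb8 was 117-fold and Hoxa3 58.5-fold higher, and Zfp703, a zinc finger gene, was 342-fold higher. Pmp22, a myelin protein gene, went from 4.40 to 9.38.

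The largest difference downward on day 1 was in Tdh, threonine dehydrogenase, an enzyme on which mouse embryonic stem cells depend, at 6.91 against 12.49, 47.7-fold lower (log2 −5.58, interval −5.94 to −5.23). Socs3, a direct STAT3 target, went from 10.94 to 7.68, and Stat3 itself from 11.40 to 9.69, while the LIF-STAT3 genes Pim1 (9.60 to 10.96) and Jak2 (7.19 to 8.32) stood above day 0. Mycn went from 11.39 to 8.02, Zfp42 (Rex1), a naive pluripotency marker, from 13.30 to 10.55, and Dnmt3l, a cofactor of DNA methylation, from 12.71 to 10.12. Sgk1, Spp1, Ifitm3, Emp1 and Fblim1 were lower by log2 differences from −2.94 for Sgk1 to −2.51 for Fblim1. In all, 91 genes were at least 4-fold higher and 21 at least 4-fold lower than on day 0, so 81.3% were higher, and with quantile normalization 44 and 33, or 57.1% higher.

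By list, the 21 retinoic acid response genes had a median day 1 difference of 3.40, above all 10000 matched random lists (percentile 100), with 16 at least 4-fold higher. The 6 Hox genes kept had a median of 6.37 (percentile 100), and the 17 extraembryonic endoderm genes one of 1.00 (percentile 100). Medians of −0.89 for 8 LIF-STAT3 genes, −0.86 for 10 core pluripotency genes and −0.83 for 8 naive pluripotency genes lay below all random lists (percentile 0). Over all 20 naive genes in the table, the filter aside, the day 1 median was −2.26, with 11 at least 4-fold lower. These single-library differences have no replicate check.

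Among the largest slopes with day were those of Pou5f1, Sox2 and Etv5 downward and of Igf2, H19 and Acta2 upward. Pou5f1, which encodes Oct4 (NM_013633, chromosome 17, 35642983 to 35647722), fell by 1.19 log2 units per day over 7 libraries (limma adjusted p = 0.0216) and by 1.43 ± 0.12 (SE) per day over days 0 to 5 (adjusted p = 0.00184). Its level went from 14.40 on day 0 to 7.66 on day 5, 107-fold lower. Sox2 fell by 0.97 per day over 7 libraries (adjusted p = 0.0218), and Etv5, an ETS factor of the FGF pathway, by 1.32 (adjusted p = 0.0147). Igf2, a fetal growth factor gene (NM_010514, chromosome 7, 149836672 to 149844709), rose by 1.51 per day (adjusted p = 0.0403) and over days 0 to 5 by 2.04 ± 0.16, from 6.33 to 15.87. H19, the imprinted noncoding RNA beside it, rose from 5.33 to 13.70 by day 5 (adjusted p = 0.0261 over 7 libraries), and Acta2, smooth muscle actin, rose by 1.86 per day (adjusted p = 0.0261).

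Further rising genes over 7 libraries were Tagln, a smooth muscle actin-binding protein (slope 1.45), Krt19, a simple-epithelial keratin (1.24), Srgn (1.11), Gstm1 (1.09), Anxa2 (1.05), Glipr1 (1.03), Pkdcc (1.02), Id3, an inhibitor of basic helix-loop-helix factors (1.01), and B2m, the light chain of MHC class I (0.98). Further falling genes were Cmah (slope −1.26), the 5-methylcytosine dioxygenase Tet1 (−1.17), Dppa2 (−1.03), the nucleoside transporter Slc29a1 (−1.02), Sall4 (−1.02), the fatty acid elongase Elovl6 (from 11.81 to 9.29 on day 5), Zscan10 (−0.97), Dppa5a (−0.96) and the amino acid transporter Slc7a5 (−0.91). Their adjusted p lay from 0.0144 for Zscan10 to 0.0441 for Tagln. The same rule over days 0 to 5 added Igfbp5, which binds insulin-like growth factors (slope 1.98), the matrix gene Ecm1 (1.96), the orphan nuclear receptor gene Nr2f2 (1.79, from 2 reads on day 0), Lhfpl2 (1.68), the collagen gene Col3a1 (1.68), the imprinted gene Dlk1 (1.48), App (1.44) and Hkdc1 (1.44). Downward it added metallothionein Mt2 (−1.19), Upp1 (−1.17), Chchd10 (−1.12), Zfp42 (7.74 on day 5) and Pfkp (−0.95).

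Over 7 libraries limma called 116 rising and 274 falling genes, 29.7% rising, and with median-centring 249 and 342, or 42.1% rising. Without day 6 it called 1858 rising and 1943 falling genes, which held all 116 and all 274 in the same direction. Of these, 1454 rising and 1799 falling genes were called again after the length correction. Leaving out other libraries removed calls: without day 0, day 1 or day 4 limma called 0 genes in either direction (1526, 1284 and 1747 at an unadjusted p under 0.05). Rising and falling calls numbered 2 and 6 without day 2, 7 and 17 without day 3, and 64 and 267 without day 5. The median length of rising genes was 1721 nt over 7 libraries and 3598.5 nt over days 0 to 5, and of falling genes 3437 and 2492 nt.

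**Figure D1:**
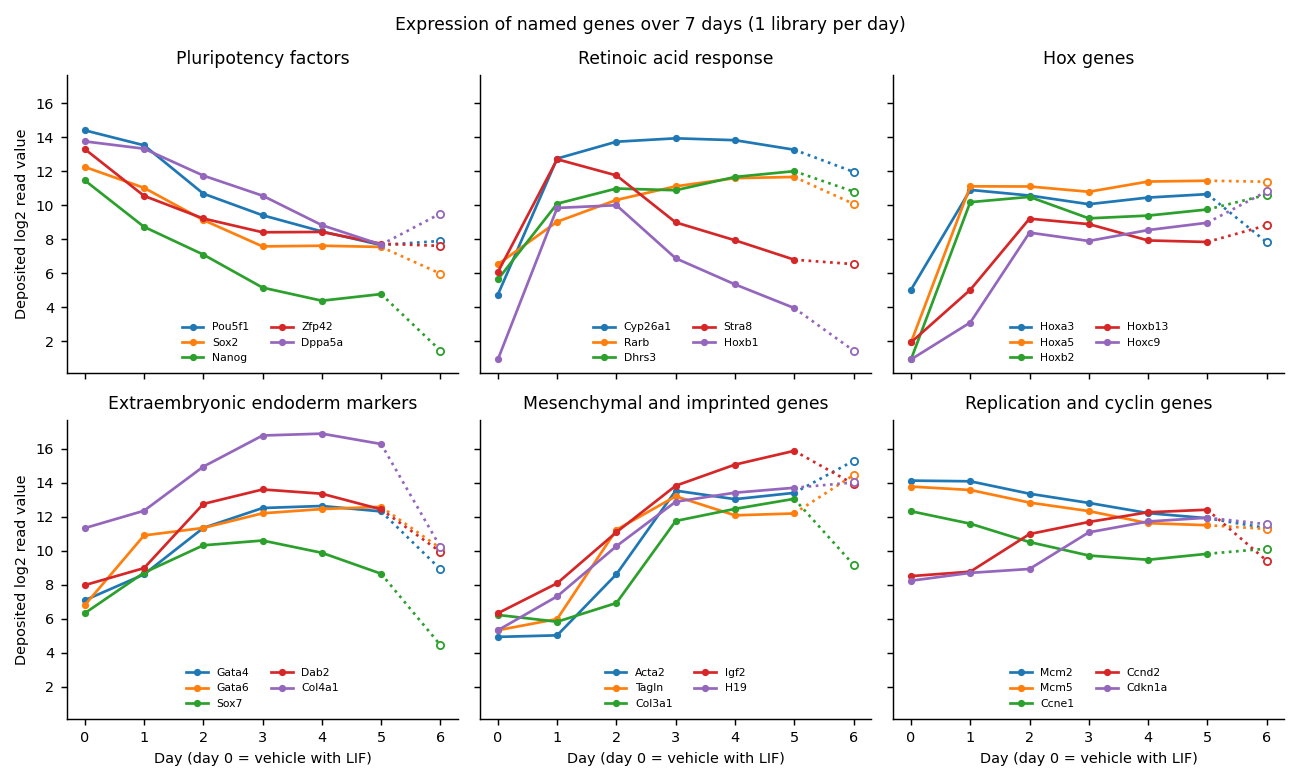
Deposited log2 read values (vertical axis) of named genes by day (horizontal axis), with 1 library and 1 point per day, for pluripotency, retinoic acid response, Hox, extraembryonic endoderm, mesenchymal and imprinted, and replication and cyclin genes. Dotted lines and open points mark day 6, and Pou5f1 goes from 14.40 on day 0 to 7.66 on day 5 while Igf2 goes from 6.33 to 15.87.

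Most core pluripotency genes kept fell. Of 10 core pluripotency genes kept, 9 fell and 0 rose over days 0 to 5, and 9 fell when adjusted over the list alone (camera adjusted p = 8.29e-05, adjusted p = 0.352 with an estimated correlation). They included the RNA-binding gene L1td1 (slope −0.69), Trim71 (−0.67) and the cell-cycle factor Mybl2 (−0.70); Tdh had a slope of −0.12 (adjusted p = 0.797) after its low on day 1. Over 7 libraries 7 of the 10 fell, 9 adjusted over the list alone (camera adjusted p = 1.41e-06, adjusted p = 0.249 with an estimated correlation). Of 8 naive pluripotency genes kept, 5 fell over days 0 to 5, also 5 adjusted over the list alone (camera adjusted p = 0.00449, adjusted p = 0.352 with an estimated correlation). Over 7 libraries 3 fell, 7 adjusted over the list alone (camera adjusted p = 0.000644, adjusted p = 0.249 with an estimated correlation). Of the 20 naive genes in the table, all 20 stood below day 0 on day 5 and 18 by at least 4-fold. Nanog, below the expression filter, went from 11.46 to 4.78 (103-fold lower), Esrrb from 13.42 to 5.16 and Tdgf1 from 13.54 to 5.35.

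All 4 FGF-ERK target genes kept fell over days 0 to 5, and all 4 adjusted over the list alone (camera adjusted p = 0.0157, adjusted p = 0.523 with an estimated correlation). They were Etv5 (slope −1.14), the phosphatase gene Dusp6 (−0.71) and the pathway inhibitors Spred2 (−0.36) and Spred1 (−0.34). Over 7 libraries 2 of them fell, 4 adjusted over the list alone (camera adjusted p = 0.00178, adjusted p = 0.494 with an estimated correlation). Of 8 LIF-STAT3 genes, Gfpt2, Pim1 and Pim3 fell and Jak2 and Il6st, the kinase and receptor subunit of the pathway, rose over days 0 to 5, with 2 up and 3 down adjusted over the list alone as well (camera adjusted p = 0.947, direction down, list median 0.082, mean −0.039). Socs3 and Stat3 were at 9.80 and 11.34 on day 5, after 7.68 and 9.69 on day 1. Among 5 formative and primed epiblast genes, Cdh2 (N-cadherin, slope 1.06) and Cldn6 (0.52) rose and Dnmt3b (−0.49) fell, unchanged adjusted over the list alone (camera adjusted p = 0.753). The whole list ran the other way: of 17 genes in the table, 10 stood at least 4-fold lower and 2 at least 4-fold higher on day 5, with a median difference of −3.31.

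Several retinoic acid response genes rose. Of 21 kept, 7 rose and 0 fell over days 0 to 5, also 7 adjusted over the list alone (camera adjusted p = 0.0108, adjusted p = 0.651 with an estimated correlation). The receptor gene Rarb, itself a receptor target, rose by 0.98 ± 0.16 per day, from 6.53 to 11.66 on day 5 (adjusted p = 0.00475), and Dhrs3 (1.04), the Hox cofactor genes Meis1 (1.03) and Meis2 (0.92), and Tgm2 (0.67) were among the others. Over 7 libraries 0 of the 21 were called, and 0 adjusted over the list alone, although camera placed the list above other genes (adjusted p = 0.00708, adjusted p = 0.607 with an estimated correlation). Cyp26a1 stood at 13.93 on day 3 and 13.26 on day 5 and had no called slope (1.31 ± 0.55, adjusted p = 0.0831), and Stra8 was back at 6.80 on day 5.

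Hox genes of all 4 clusters were above day 0 on day 5. Cluster D was represented by Hoxd4 alone, with 8 reads on day 0, 9 on day 1 and 142 on day 5. The table held 26 of the 39 Hox genes of the fixed list. All 26 stood at least 4-fold higher on day 5, 22 of them already on day 1, and most started from few reads, 1 read in Hoxb1 and Hoxb2. Hoxb1 stood at 9.84 on day 1, was little different on day 2 and was back at 3.96 on day 5, while Hoxa5 stayed between 10.79 and 11.44 from day 1 to day 6. None of the 6 Hox genes kept had a called slope in either fit, adjusted over the list alone included; camera gave an adjusted p of 0.0143 over 7 libraries (adjusted p = 0.593 with an estimated correlation) and 0.160 over days 0 to 5. The day of half-maximal rise was tested against paralog number, the order in which clusters open along the chromosome. In the 6 kept genes rho was 0.71 (exact permutation p = 0.136, two-sided), and −0.15 (exact permutation p = 0.817) with the day of the highest value instead. The 6 kept genes lay from 0.50 (Hoxa3) to 0.65 days (Hoxb9). Over all 26 listed Hox genes, a set chosen after the data were seen, rho was 0.56 (permutation p = 0.00334), with Hoxb2 at 0.52, Hoxb13 at 1.13, Hoxc6 at 1.57 and Hoxc13 at 1.93 days. Others ran against the order, such as Hoxa10 at 0.56 and Hoxd4 at 1.64 days. Clusters C and D were present only from Hoxc4 and Hoxd4 on, so the pooled rho mixes cluster with paralog number. With daily libraries a value under 1 says only that the midpoint was crossed by day 1, and neighbouring Hox genes overlap and are not independent.

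Extraembryonic endoderm genes, which mark the yolk sac lineages, formed the group with the largest median slope among the 20 lists over days 0 to 5 (0.97). Of 17 kept, 14 rose and Apoe fell, the same counts adjusted over the list alone (camera adjusted p = 0.0007, adjusted p = 0.523 with an estimated correlation). The transcription factor genes Gata4 (1.12 ± 0.22, adjusted p = 0.00711) and Gata6 (0.98 ± 0.25, adjusted p = 0.0165) went from 7.09 to 12.31 and from 6.80 to 12.58 on day 5. The basement membrane genes Col4a1 and Col4a2 both had slopes of 1.15, Col4a1 reaching 16.88 on day 4, and Plat (1.41), Dab2 (1.03), Lamb1-1 (0.97) and Sparc (0.95) rose too. Sox7 stood highest on day 3 at 10.60. Over 7 libraries 1 of the 17 rose (Srgn) and 1 fell (Apoe), the same adjusted over the list alone (camera adjusted p = 0.00881, adjusted p = 0.607 with an estimated correlation); on day 6 Col4a1 was at 10.22 and Gata4 at 8.91.

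Most markers of fibroblasts, fixed as a list of another cell type, rose as well. Of 8 kept, 7 rose over days 0 to 5, also 7 adjusted over the list alone (camera adjusted p = 0.00209, adjusted p = 0.496 with an estimated correlation), and over 7 libraries Acta2 and Tagln, 2 adjusted over the list alone (camera adjusted p = 0.00427, adjusted p = 0.593 with an estimated correlation). The collagen genes Col3a1, Col1a1 (slope 0.97), Col1a2 (0.79) and Col5a1 (0.50) were among them, and Fn1 was at 14.28 on day 0, 14.70 on day 5 and 9.08 on day 6. Among 6 neural progenitor genes, Sox11 (0.81), Nes (0.66), Ncam1 (0.60) and Vim (0.57) rose and Gbx2 (−0.78) fell over days 0 to 5, unchanged adjusted over the list alone (camera adjusted p = 0.192). The neural factors Sox1 and Pax6, below the filter, peaked at 8.86 on day 1 and 9.60 on day 2. Of 4 neuron genes Dcx rose (0.26), also adjusted over the list alone, but not after the length correction (adjusted p = 0.119), and Tubb3 had a slope of 0.031 ± 0.071 (adjusted p = 0.729); camera gave an adjusted p of 0.954, direction up, against a list median of −0.017 and a mean of −0.11. Of all 18 neuron genes in the table, most of them below the filter, 9 stood at least 4-fold higher and 1 lower on day 5, among them Onecut2 (4.53 to 10.80) and Neurog1 (2.53 to 7.18).

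**Figure D2:**
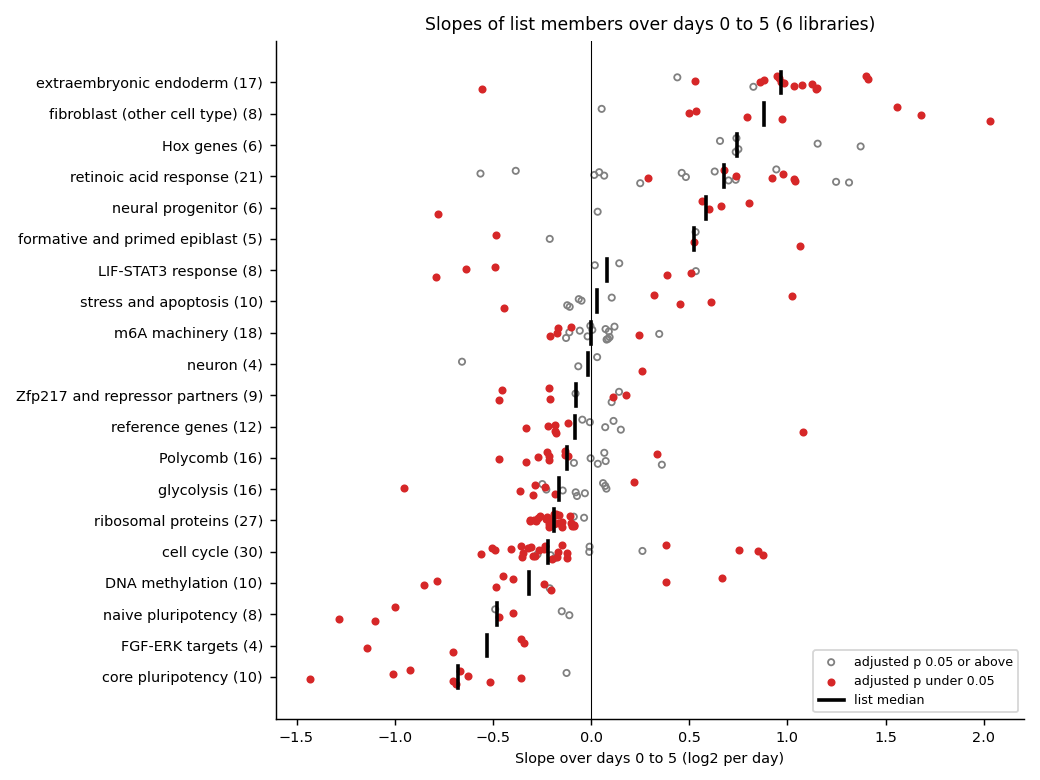
Slope over days 0 to 5 (horizontal axis, log2 units per day, 6 libraries) of each kept gene of the 20 tested lists (vertical axis, number of genes in parentheses), filled where the limma adjusted p was under 0.05, with a bar at the list median. The median is 0.97 for extraembryonic endoderm and −0.68 for core pluripotency.

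Most cell-cycle genes kept fell over days 0 to 5. Of 30 cell-cycle genes kept, 20 fell and 4 rose, and 22 fell and 5 rose adjusted over the list alone (camera adjusted p = 0.0015, adjusted p = 0.523 with an estimated correlation). Helicase subunit genes Mcm5 (slope −0.51) and Mcm2 (−0.49), the cyclin genes Ccne1 (−0.56) and Ccnb1 (−0.29) and Cdc20 (−0.35) fell. The 4 rising genes were Ccnd2 (0.88), the inhibitor genes Cdkn1a (0.85) and Cdkn2a (0.75), and Rb1 (0.38). The proliferation marker gene Mki67 had a slope of −0.0074 (adjusted p = 0.929), Aurkb one of −0.18 (adjusted p = 0.0531) and the inhibitor gene Cdkn1b one of 0.26 (adjusted p = 0.0503). Over 7 libraries 6 fell and 2 rose, Cdkn1a and Cdkn2a, and 15 and 2 adjusted over the list alone (camera adjusted p = 0.00708, adjusted p = 0.494 with an estimated correlation).

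Of 10 DNA methylation genes, 7 fell and 2 rose over days 0 to 5, the same adjusted over the list alone: Dnmt3l (slope −0.85), Tet1 (−0.78), Dnmt3b (−0.49), Uhrf1 (−0.45) and Tet2 (−0.40) were among those that fell, and Tet3 (0.67) among those that rose. Camera called the list downward over 7 libraries, where 4 fell and 7 adjusted over the list alone (adjusted p = 0.00328, adjusted p = 0.494 with an estimated correlation), and not without day 6 (adjusted p = 0.0574). Of 16 Polycomb genes, 9 fell, with Jarid2 (−0.47) and Ezh2 (−0.21), the methyltransferase gene, and Rbbp7 rose (0.33), the same adjusted over the list alone. Over 7 libraries none of the 16 was called, and 1 rose and 4 fell adjusted over the list alone (limma; camera adjusted p = 0.0439, adjusted p = 0.593 with an estimated correlation), against a camera adjusted p of 0.156 without day 6.

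Ribosomal protein genes fell by small amounts until day 5 and stood higher on day 6. By day 5, 25 of 27 fell and 26 adjusted over the list alone (median slope −0.19, camera adjusted p = 2.17e-07, adjusted p = 0.496 with an estimated correlation), with Rpl8 and Rplp1 at −0.31; 21 fell after the length correction and 26 after median-centring. Over 7 libraries 0 were called, 0 adjusted over the list alone, and camera placed the list upward (adjusted p = 0.0013, adjusted p = 0.607 with an estimated correlation): the day 6 library decided that direction, its median difference from day 0 being 1.92, and 0.31 after the length correction. Many ribosomal protein genes have near-identical pseudogenes, so reads can be shared. Of 16 glycolysis genes, 6 fell, led by the phosphofructokinase gene Pfkp and with Hk2 (slope −0.36) and Pkm2 (−0.29), and Tpi1 rose (0.22) over days 0 to 5, the same adjusted over the list alone (camera adjusted p = 0.0758).

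Of 10 stress and apoptosis genes, 4 rose and 1 fell over days 0 to 5, and 4 and 2 adjusted over the list alone (camera adjusted p = 0.556). The p53-inducible genes Ccng1 (slope 0.61), Bbc3 (0.46) and Mdm2 (0.32) and the AP-1 gene Jun (1.03) rose, and Asns, asparagine synthetase, fell (−0.44). Of 12 reference genes, 6 fell, Actb and Gapdh by 0.18 per day each, and B2m rose by 1.08, the same counts adjusted over the list alone (camera adjusted p = 0.339, direction down, list median −0.081, mean 0.013). Over 7 libraries camera called none of the lists for m6A, Zfp217 partners, LIF-STAT3, formative, neural progenitor, neuron, stress, glycolysis or reference genes, with adjusted p from 0.0641 for m6A and for neuron to 0.853 for reference genes. Its direction was up for reference genes against a list median of −0.087 and a mean of −0.015, and up for neural progenitor genes against a median of 0.093 and a mean of −0.0069.

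Fry, which does not compare a list with other genes, differed from camera for several lists. It called 7 lists over 7 libraries, among them glycolysis (adjusted p = 0.00743) and Zfp217 partners (adjusted p = 0.00765), both downward and not called by camera. It did not call the lists for retinoic acid response (adjusted p = 0.59), Hox (adjusted p = 0.363), extraembryonic endoderm (adjusted p = 0.606), fibroblast (adjusted p = 0.22), Polycomb (adjusted p = 0.0648) or ribosomal protein genes (adjusted p = 0.59), which camera called. Without day 6 fry called 12 lists, of which camera did not call DNA methylation (fry adjusted p = 0.00228), Polycomb (0.0142), reference (0.0142), glycolysis (0.0217) and neural progenitor genes (0.0351), the last of them upward. The retinoic acid response list, called by camera, had a fry adjusted p of 0.128 there.

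Among genes kept that the F-test of day and day squared called over days 0 to 5, few had peaked and come down again by day 5. Over 7 libraries limma's F-test of day and day squared called 2535 genes, and 303 of them stood highest on an inner day, at least 2 log2 units above both day 0 and day 6, so these peaks rest on the low day 6 values, and 114 of them were highest on day 5. The naming rule took from them Sfrp5, a Wnt antagonist (6.40 on day 0, 12.17 on day 4, 7.50 on day 6), Foxq1 (3.75, 10.98 on day 3, 6.82 on day 6), Sox7, Nr2f2, the tissue factor gene F3, Meis1, Jun and Gas1, with adjusted p from 0.0109 to 0.0149; Jun (11.02) and Meis1 (11.27) stood highest on day 5. A comparison added later used the F-test over days 0 to 5 with day 5 as the end, so the genes called differ from the 2535. In it 5 genes peaked, among them the endocytic receptor genes Cubn (9.48 on day 0, 15.05 on day 3, 12.69 on day 5) and Lrp2 (11.70, 14.04 on day 3, 11.56 on day 5), and 3 dipped. The dips, lowest on day 2, were Ccnd1, cyclin D1 (11.57, 7.81, and 10.31 on day 5), Cpt1a, a mitochondrial fatty acid importer (10.28, 7.97, 10.65), and Pcolce (11.59, 7.50, 10.25). These counts miss kept genes that the F-test did not call, such as Tdh (12.49, 6.91 on day 1, 9.35 on day 5). They also miss early peaks below the filter, such as Hoxb1, Lefty1 and Cdx1. Without day 6 the F-test called 3794 genes, without day 5 5682, and without day 4 0 (3002 at an unadjusted p under 0.05). It called 17 without day 0, 34 without day 1, 47 without day 2 and 14 without day 3.

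Among the genes kept, Acta2, Hoxb2 and Hoxa5 had the largest differences upward on day 6, and Tet1, Cdh1 and Etv5 the largest downward. Acta2 was 1294-fold higher (log2 10.34, counting interval 9.64 to 11.14), Tagln 550-fold, H19 408-fold, Igf2 192-fold, Id3 148-fold and Krt18 126-fold. Hoxb2 (815-fold, from 1 read), Hoxa5 (692-fold, from 2), Cyp26a1 (148-fold) and Nr2f2 (log2 6.65, from 2 reads) were also among the 10 largest. Lowest of the genes kept were Tet1 (log2 −9.03, 11 reads on day 6), Cdh1, which encodes E-cadherin (−8.32, 8 reads), Etv5 (−8.31), BC032203, Cmah, Tcfcp2l1, Sall4, Ino80d, Rest and Sall1. Genes below the filter were lower still, such as Tdgf1 (−10.09, 4 reads on day 6) and Nanog (11.46 on day 0, 1.46 on day 6). On day 5 the same difference was −4.11 for Tet1, −2.62 for Cdh1 and −0.49 for Ino80d. Of the genes higher on day 6, it was 8.46 for Acta2 and 6.85 for Tagln (9.1 on day 6). For Cyp26a1 it was larger on day 5, at 8.51 against 7.21.

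In counts, 574 genes were at least 4-fold higher and 2161 at least 4-fold lower on day 6 than on day 0, 21.0% higher, with median lengths of 1166 and 4604 nt. With day 5 in place of day 6 the counts were 618 and 186. The median of all genes kept was lower by 0.88 on day 6 (difference −0.88): median-centring gave 1268 and 1165 genes (52.1% higher), quantile normalization 698 and 697 and the length correction 642 and 553 (53.7%). Retinoic acid response genes (median difference 2.08, percentile 100) and Hox genes (4.50, percentile 100) stood above matched random lists on day 6, and core pluripotency (−6.25, percentile 0) and naive pluripotency genes (−5.62, percentile 0) below them. After the length correction these medians were 3.54, 5.23, −4.82 and −5.22. Extraembryonic endoderm genes were near the middle (−0.73, percentile 55.8, and 1.44 after the length correction), against 4.31 (percentile 100) on day 5.

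Zfp217 (NM_001159683, chromosome 2, 169934142 to 169968175) declined modestly until day 5. Its log2 values were 10.84 on day 0, 10.75, 10.54, 9.91, 10.04 and 9.91 on day 5, and 5.46 on day 6, where 16 reads were counted against 957 on day 0. Day 5 lay 1.92-fold below day 0 (log2 −0.94, counting interval −1.07 to −0.80), while day 1 did not differ beyond counting error (−0.090, interval −0.22 to 0.039). Over days 0 to 5 its slope was −0.21 ± 0.045 (limma adjusted p = 0.0094), and −0.66 ± 0.22 over 7 libraries (adjusted p = 0.12), where day 6 widened the scatter. Pearson r with day was −0.75 (exact permutation p = 0.00198) and Spearman rho −0.96 (exact permutation p = 0.00278) over 7 libraries, and r was −0.88 without days 0 and 6. Without day 6, r was −0.92 (exact permutation p = 0.0139).

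**Figure D3:**
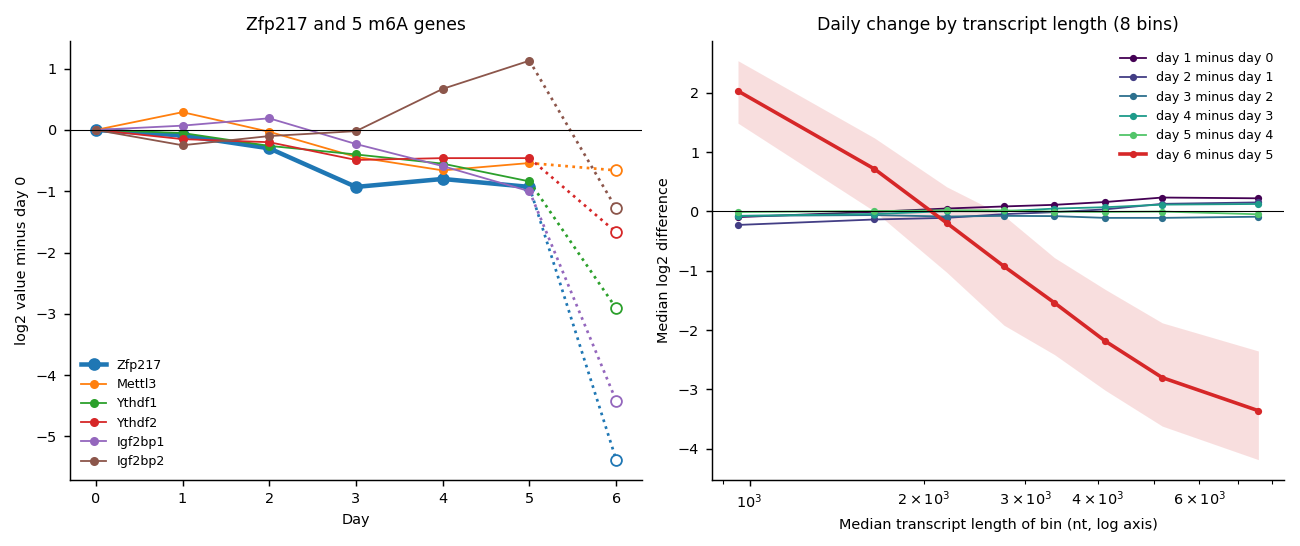
Left, log2 value minus day 0 (vertical axis) of Zfp217 and 5 m6A genes by day, 1 library per day, with day 6 as open points. Right, median daily log2 difference (vertical axis) in 8 bins of transcript length (horizontal log axis, nt), with the quartiles of day 6 minus day 5 shaded, which goes from 2.03 at a median of 955 nt to −3.36 at 7592.5 nt.

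Zfp217 works with the LSD1-CoREST and CtBP repressor proteins, whose genes moved in both directions. Without day 6, 4 of 9 list genes, Zfp217 among them, fell and 2 rose, 4 and 3 adjusted over the list alone (camera adjusted p = 0.704). Of all 7242 genes kept, 1943 fell and 1858 rose in that fit. Ctbp2 (slope −0.47), Rcor2 (−0.45), Zfp217 and the deacetylase gene Hdac1 (−0.21) fell, and Hmg20b (0.18) and Hdac2 (0.11) rose. After median-centring 1 rose, and so after the length correction, where Hdac2 had an adjusted p of 0.0920. Over 7 libraries Rcor2 and Ctbp2 fell (2 called, 2 up and 3 down adjusted over the list alone). The demethylase gene Kdm1a, LSD1 itself, went from 11.66 to 11.47 by day 5 (slope −0.079, adjusted p = 0.192).

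Few genes of m6A writing, erasing and reading passed the test. Over days 0 to 5, 4 of 18 fell and 1 rose, and 2 adjusted over the list alone (camera adjusted p = 0.947, direction down, list median 0.0015, mean 0.0096). The reader genes Ythdf1 (slope −0.17, adjusted p = 0.00516), Ythdf2 (−0.10, adjusted p = 0.0385) and Igf2bp1 (−0.21, adjusted p = 0.0157) and the methyltransferase gene Mettl3 (−0.17, adjusted p = 0.029) fell, and Igf2bp2 (0.24, adjusted p = 0.0236) rose. After the length correction 6 fell and 0 rose, Igf2bp2 having an adjusted p of 0.0763, and after median-centring 6 fell and 1 rose. The largest slope of the list was that of Igf2bp3, which went from 10.39 to 12.10 on day 2 and 11.78 on day 5 (0.35 ± 0.12, adjusted p = 0.0529). The eraser genes Fto and Alkbh5 had slopes of 0.095 (adjusted p = 0.0832) and 0.086 (adjusted p = 0.102), and Mettl14, below the filter, went from 8.52 to 8.16 on day 5.

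Over 7 libraries limma and limma-voom each called 0 of the 18, also 0 adjusted over the list alone, with 6 at an unadjusted p under 0.05. By exact permutation of 7 days, 8 of 19 listed m6A genes had a Pearson r with an adjusted p under 0.05 over the list, Ythdf1 falling on every day (r −0.81, exact permutation p = 0.0004, the smallest this test can give, adjusted p = 0.00754; r −0.99 without days 0 and 6). By Spearman rho only Ythdf1 did (adjusted exact permutation p = 0.00754). With day 6 left out a single gene could not pass, because the smallest possible exact permutation p of 0.00278 is 0.0528 when adjusted over 19 genes, which Ythdf1 reached (r −0.98), with 7 genes at an unadjusted p under 0.05. All 8 were negative and include day 6, where 18 of the 19 stood below day 0; the median difference of the 18 kept was −1.83 there, and −0.57 after the length correction. These 19 relations and that of Zfp217 rest on 7 unreplicated libraries.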

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

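No paired analysis was possible because each day had 1 library and the labels pair none. The fits with a length correction, median-centring of days 0 to 5, limma-voom, every listed Hox gene and day 5 in place of day 6 were chosen after seeing the data, and the others before. With 1 library left out at a time, rising genes numbered 0 to 1858, falling genes 0 to 1943 and genes with a straight or curved course 0 to 5682, called m6A genes 0 to 5, and the slope of Zfp217 ran from −0.81 to −0.21. Fewer libraries leave less power, but leaving out day 6 raised the counts, so power alone does not explain the range. Whether it explains the counts of 0 was not tested. Rising genes stayed within 1.5 times the count given in the report in 6 of 21 settings, falling genes in 9 of 21 and straight or curved courses in 9 of 20.

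Rising genes numbered 249 with median-centring, 219 with quantile normalization, 311 without a filter and 70 with the filter at the 60th percentile. With the length correction there were 632 rising and 843 falling genes, and 1538 and 2292 when day 6 was left out as well. Without day 6, median-centring gave 1622 and 2348 and limma-voom 1940 and 1806. Falling genes numbered 628 without a filter and 110 against log2 of day plus 1. Genes with a straight or curved course numbered 4836 without a filter, 1672 at the 60th percentile, 29 against log2 of day plus 1, and without day 6 3875 (length-corrected) and 3990 (median-centred). The filters tested more or fewer genes; for the other settings the cause was not tested.

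Called m6A genes numbered 0 in the report's fit, 1 with median-centring, 3 with the length correction, and without day 6 also 6 (length-corrected), 7 (median-centred) and 4 (limma-voom). The slope of Zfp217 was negative in every setting and passed the threshold at −0.45 with quantile normalization, −0.44 length-corrected, and without day 6 at −0.32 (length-corrected), −0.24 (median-centred) and −0.20 (limma-voom). Camera called 18 lists without a filter, where 27 were tested, and stayed within 1.5 times of its 11 lists in the other 19 settings. With an estimated correlation between genes it called 0 lists in the report's fit. The cause of these shifts was not tested.

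For day 1, quantile normalization gave 44 higher and 33 lower genes, no filter 268 and 134, and a 2-fold limit 439 and 142, and the filter at the 60th percentile 51 higher genes. For day 6, median-centring gave 1268 higher and 1165 lower genes, no filter 1152 and 3269, a 2-fold limit 1377 and 3446, and the filter at the 60th percentile 356 higher genes. Lower genes numbered 697 with quantile normalization, 553 with the length correction and 186 with day 5 in place of day 6. The Hox order turned to a rho of −0.15 with the day of the highest value, and was 0.56 over every listed Hox gene and, by cluster alone, 0.73 in B (permutation p = 0.0205), 0.48 in A (permutation p = 0.243) and 0.75 in C (permutation p = 0.0663); the cause was not tested. The planned run on each cluster alone was not run, since no cluster had enough genes kept. The step from day 5 to day 6 was 5.25 times the next largest by 1 minus Spearman correlation and 1.83 times after the length correction. Depth limits the low end: on day 6 the median transcript had 90 reads, and genes without a read on some day were not analysed here or stand at 1 read.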

Other observations

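Among gene groups with too few genes above the filter for a test, markers of several germ layers stood above day 0 by day 5. All genes in this paragraph and the next were picked after their values were seen. The table held only part of the fixed lists: 9 of 18 mesoderm, 11 of 15 definitive endoderm, 10 of 15 neural crest and mesenchyme and 5 of 12 trophectoderm genes. Among the genes kept, 8.5% were at least 4-fold higher and 2.6% lower on day 5. Of 9 mesoderm genes in the table, 6 were at least 4-fold higher and 0 lower, among them the forkhead gene Foxc2 (0.94 on day 0, 10.55 on day 5) and Hand2 (0.94, 8.55), which act in mesoderm and heart. Both had 1 read on day 0. Of 11 definitive endoderm genes 9 were at least 4-fold higher and 1 lower, with Foxa2 (3.75, 9.90), Sox17 (4.11, 7.97) and the keratin gene Krt18 (6.07, 11.92) higher and Epcam lower (9.36, 6.81). Several of these genes are active in extraembryonic endoderm too. Of 10 neural crest and mesenchyme genes 7 were higher and 1 lower, with Twist1 (5.26, 9.96), Sox9 (4.94, 9.85) and Ednra (2.94, 10.92) higher and Ngfr lower (10.35, 6.45). Of 5 trophectoderm genes 3 were higher, Gata3 (3.53, 9.95), Gata2 (6.80, 10.83) and Fgfr2 (7.45, 11.08).

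Of 12 germline and 2-cell-like genes 0 were higher and 2 lower by 4-fold on day 5, and of 11 Wnt target genes 3 were higher and 3 lower. Of 5 endothelial and blood genes 1 was higher and 1, Pecam1 (10.11, 5.68), lower, and neither of the 2 listed histone genes differed by 4-fold. The fixed lists were longer, with 17 germline and 2-cell-like, 15 Wnt target, 12 endothelial and blood and 22 histone genes. Some genes were high early only: Lefty1, a Nodal antagonist, went from 8.48 to 12.21 on day 1, 11.07 on day 2 and 3.43 on day 5, and Cdx1, a caudal homeobox gene that retinoic acid induces, from 4.75 to 9.51 on day 1, 6.07 on day 2 and 1.26 on day 5. Nodal itself was at 9.95 on day 0, 10.17 on day 1 and 2.26 on day 5.

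For the weighing below, the length test and the continued-change test of the day 6 library were chosen only after seeing the result, and the other tests were written down before their values were known. No biological explanation was tested for the ribosomal protein genes or for Zfp217. The day 6 minus day 5 difference followed transcript length (rho −0.7766), and the length correction removed 62.5% of its variance. This is in line with unequal recovery of long and short transcripts on day 6. GC content beyond length gave a rho of −0.1627, between the limits set beforehand, so its part cannot be told apart. Continued change along the course of days 0 to 4, as the main cause, would need a positive correlation, and the value was −0.3142. Over the genes kept, the length-corrected day 6 minus day 5 difference therefore ran against that course on balance. Continued change in part of the genes is not excluded, because any library effect that the length correction left in place enters the correlation too. Why recovery would differ, through RNA quality or library preparation, was not tested.

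The fall of ribosomal protein genes up to day 5 had a median slope of −0.19. After the length correction it was −0.1101, 58.8% of the first value. By the limit set beforehand, the length trend that this correction removes may account for part of the fall and not for all of it. A length effect that the correction left in place is not excluded. With median-centring it was −0.2175, so the factor per library that evens the medians does not account for it. Other factors were not tried. On day 5 random lists matched on mean expression had a median difference from day 0 of −0.42, against −0.83 for these genes (percentile 0.81). Their median rise of 2.71 from day 5 to day 6 was 0.72 after the length correction.

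Zfp217 was lower by 4.45 log2 units on day 6 than on day 5 (difference −4.45), at percentile 11 of the 200 genes nearest in length, from 5467 to 5895 nt. Those genes had a median of −3.01 with an SD of 1.37. After the length correction a difference of −1.62 was left, so transcript length may explain most of the day 6 value, while a change of Zfp217 itself is neither shown nor excluded, and the decline up to day 5 is the part that does not rest on that library.

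The order of the libraries was permuted and trend genes were called again. Over 7 libraries 2 of 100 orders, the real one included, gave as many as the real 390, and the highest other gave 1257, with the day 6 library placed before day 0 and days 4 and 5 exchanged. Over days 0 to 5 only the real order reached 3801 (1 of 100), and the highest other gave 3066. Both fits were within the limit set beforehand against a chance order, but an order with several times as many calls points to structure among the 7 libraries besides time. Staying within the limit does not set time apart from any other steady drift between libraries of neighbouring days.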
